A study of Mus musculus with 6 samples.

How the data were processed

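Total RNA from 6 samples of mouse cells was measured on Agilent 1-colour whole-genome arrays, with 1 array per sample and 41174 probes in 43379 spots that were not controls. Per the file headers, each scanner file held spot intensity values from Agilent Feature Extraction, with spatial detrending, background subtraction, a surrogate value for spots not above background, and no normalization between arrays. The deposited processed table held a ratio: the background-subtracted signal divided by a constant of its array, so that each column had a median of 1. This was tested on the values: all 41529 entries of each column matched exactly 1 spot at a tolerance of 1e-06, and 8.01% to 10.1% of the entries stood at a small positive floor. Both kinds of deposited file held a quality score per spot, whose making the authors did not state and which served only to match entries to spots.

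Intensities were taken to the log2 scale and each array's 75th percentile was set to 0. Probes well above background on at least 2 of the 6 arrays were kept, which left 30214 probes. Names came from the accession for 22951 probes, from the symbol or a synonym for 9755, and from the array's own annotation alone for 8468. A gene table for GRCm38.p6 served only for names, chromosomes and gene order. Where a gene had several such probes, as 6940 genes did, the brightest was used, which gave 20220 genes. The number of arrays limits the precision of every value.

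Linear models were fitted with limma 3.58.1 in R 4.3.3, with moderated variances and Benjamini-Hochberg adjusted p under 0.05 as the threshold; every test was two-sided. The knockdown comparison set 4 knockdown arrays against 2 control arrays with day as a term, and the same fit gave day 12 against day 9. A fit with 4 groups gave the knockdown effect at each day and the difference between these effects; it assumes that the lone control array of a day varies like the knockdown pairs. A fit with day and vector gave hairpin 2 against hairpin 1. Each day's 3 arrays shared 1 slide and 1 scan, so day and slide cannot be told apart, and day as a term is already the slide block; the knockdown and hairpin contrasts lie within slides. Control, hairpin 1 and hairpin 2 took positions 2, 3 and 4 on both slides, so vector and position cannot be told apart either. The labels do not say that the samples came from separate cultures, so the p-values measure only the spread between these samples.

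Whether the vectors pair the arrays across the days was checked by correlating, across genes, each array's deviation from its day's mean. Arrays with the same vector, which also shared a position on the slide, gave r of 0.38, 0.54 and 0.26. Arrays with different vectors gave -0.34 to -0.02, where deviations from a shared mean push values below 0. The vector was therefore also fitted as a replicate block, which gave 20 genes for the knockdown contrast and 328 for the day contrast. In that fit the difference between the hairpins is no longer part of the spread, so its p-values do not cover how far 2 hairpins differ.

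Before the data were examined, 28 gene lists, the alternatives and the rule for named genes were fixed. Lists were tested against all other genes with camera, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 28 lists. An estimated correlation was the alternative. With it, camera also falls back on the residual degrees of freedom, 3 for the knockdown and day contrasts and 2 for the others, so few lists can pass. For the endoderm list in the knockdown contrast the estimate was -0.02, below the preset, yet the camera p went from 5.48e-08 to 0.0091. A call lost this way therefore does not by itself show that correlation between genes made it. Other lists had estimates above the preset in the knockdown contrast. They were 0.62 for two-cell, 0.51 for interferon, 0.38 for fibroblast, 0.22 for immediate early, 0.15 for DAZL target and 0.07 for germ cell genes. If these estimates hold, the p-values with the preset are too small for such lists. A call lost there may come from correlation, from few degrees of freedom or from both. Members past the threshold were counted over all genes tested and adjusted over the list alone. Dazl was named first. For the knockdown and day contrasts, up to 12 genes per direction were named by size of change among those past the threshold that moved the same way in every pair and had a gene symbol. Places left over went to the smallest unadjusted p among genes that moved the same way in every pair and differed at least 2-fold in the fit. The text says that these did not pass. For the other contrasts up to 5 genes per direction past the threshold, or else the 3 of smallest p, were named, and for each list up to 4 members of largest change. Some members that the rule would name are not reported here. Genes outside the rule are said to have been chosen after their values were seen.

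Genes that differed at least 2-fold the same way in all 4 pairs of a knockdown array and its control were counted without a test. This count, and the correlation across genes of the day 9 and day 12 effects, were repeated with each hairpin in the control's place. A simulation without any effect gave the count that array spread alone yields, from 100 draws. Where no array of an arm was well above background, a fold is given as "at least": the mean of the bright arm against, per array of the other arm, the higher of its own value and the lowest signal well above background. Of the list members given with a difference, Lum and Mx1 were well above background on 4 of the 6 arrays and Tpbpa, Dcn and Arg2 on 5.

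The alternatives were normexp background correction (offset 50) on the raw signals, quantile normalization, probes well above background on all 6 arrays, no filter, the mean of all probes of a gene, the authors' deposited table (pseudocount 0.05, 19018 genes), the vector as a replicate block (20 genes for the knockdown contrast), an intensity trend with a robust prior, and each array left out in turn. Leaving out the genes of chromosome 1 was added after seeing the data. Normexp moved the median of all genes by 0.12 for the knockdown contrast and -0.12 for the day contrast, on the log2 scale, so that changes under it are to be read relative to these shifts. The 7 spike-in probes, read after scaling, had median knockdown minus control differences of 0.21 and -0.04 for hairpins 1 and 2 at day 9 and of 0.29 for each at day 12.

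The fits were tested on simulated data with 200 changed genes of 20220 in each of 10 draws, with gene variances drawn around the real ones and genes independent of each other. For the knockdown contrast 20.0% of genes changed 2-fold were recovered, 83.2% at 4-fold, 96.8% at 8-fold and 98.4% at 16-fold. The day contrast recovered 28.0%, 86.8%, 95.8% and 98.0%, and the hairpin contrast 0.2%, 64.4%, 88.4% and 97.2%, at these folds. Within 1 day the recovery was 0.0%, 29.4%, 78.0% and 90.0% at day 9 and 0.2%, 31.6%, 79.0% and 92.2% at day 12. The difference between the days recovered 0.0%, 0.0%, 3.4% and 26.4%. With the Benjamini-Hochberg adjustment these shares depend on how many genes change, so they do not hold for a contrast with fewer changes. In the real knockdown contrast Dazl, 19.7-fold lower, had an adjusted p of 0.0864 with limma. The 0 genes called there therefore do not show that changes of these sizes are absent. The germ cell list, lowered 2-fold on purpose, was recovered in 10 of 10 draws for each contrast. In the real knockdown contrast its median log2 difference was only -0.49, so the draws do not show how often shifts of that size or smaller are found.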

Results

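Gene expression was measured in 6 samples of male mouse primordial germ cells that were made in culture from embryonic stem cells with a GFP reporter of Oct4 (Pou5f1). The cells carried a control vector or 1 of 2 short hairpin vectors against Dazl, which encodes an RNA-binding protein of germ cells, and each vector also carried a tdTomato marker. After 9 or 12 days of differentiation, cells positive for both colours were sorted. Each day had 1 control array, 1 array of hairpin 1 and 1 array of hairpin 2. The 75th percentile of the processed signal was 629, 656 and 745 for control, hairpin 1 and hairpin 2 at day 9, and 700, 685 and 636 at day 12. Between 70.3% and 73.3% of the probes were well above background on each array, and Pearson's r between arrays, across genes, was 0.98 to 0.99.

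The first comparison asks how far the hairpins lowered their target. Dazl (NM_010021, chromosome 17) was measured by 2 probes, and both were far lower on all 4 knockdown arrays than on the control array of the same day. Probe A_51_P246060 kept 4.46% and 4.19% of the control signal for hairpins 1 and 2 at day 9, and 3.71% for hairpin 1 at day 12, where hairpin 2 had a signal of 36.3 against 1330 in the control. Probe A_52_P271166 kept 4.84% and 8.28% at day 9, and 3.54% and 4.67% at day 12. Control signals were 499 and 1570 on these probes at day 9, and 1330 and 4190 at day 12. Relative to the array's 75th percentile, log2 values on the first probe were -4.42 ± 0.53 (SD, n = 4) in knockdown and 0.30 ± 0.89 (SD, n = 2) in control arrays. On the other probe they were -2.35 ± 0.51 (SD, n = 4) and 1.95 ± 0.89 (SD, n = 2).

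Tested over 30190 probes with limma, A_51_P246060 fell by 4.72 (SE 0.17, 26.3-fold, adjusted p = 0.0046). A_52_P271166, the brighter probe and so the one that stands for the gene, had a log2 difference of -4.30 (SE 0.29, adjusted p = 0.0547). Over 20220 genes the adjusted p of Dazl was 0.0864, and 0.0104 with the vector as a replicate block, where the SE was 0.20. Dazl had the smallest p of all genes in this contrast, and its adjusted p was 0.0276 with normexp, 0.0366 with the strict filter, 0.0066 with the mean of both probes, 0.0497 on the authors' table and 0.0172 with a trend and robust prior. Leaving out 1 array in turn gave log2 differences of -4.62 to -3.98.

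**Figure D1:**
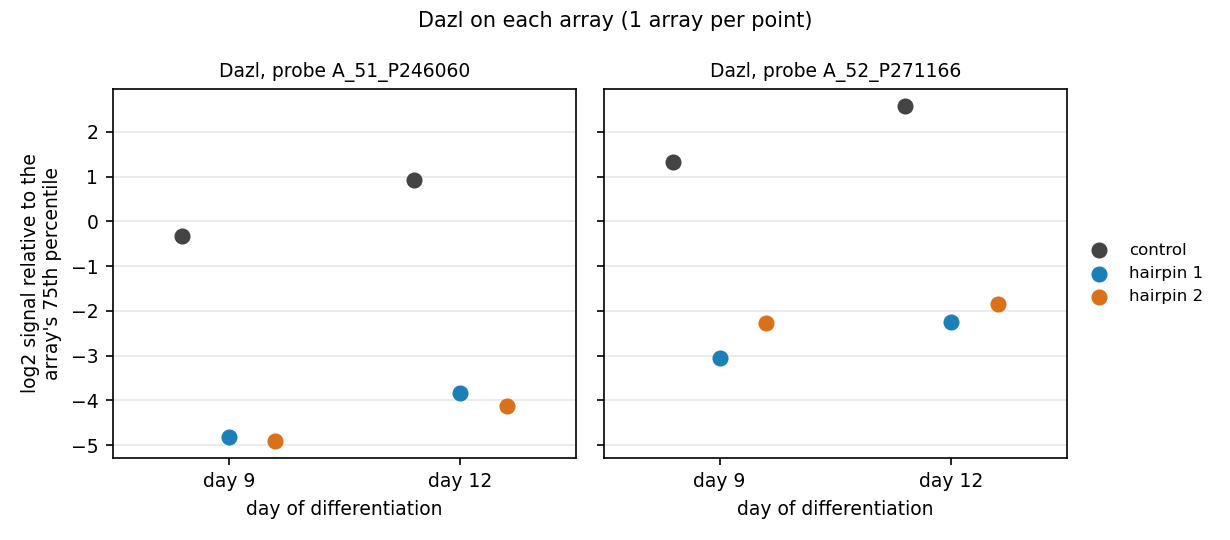
Dazl on each array, 1 panel per probe: the vertical axis is the log2 processed signal relative to the array's 75th percentile, the horizontal axis the day, and each point 1 array coloured by vector. On each probe and day the 2 knockdown points lie below the control point, with at most 8.28% of the control signal left.

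The main comparison, knockdown against control over both days, asks what else differs in cells with little Dazl. Genes of germ cell development and meiosis were lower, and markers of endoderm and of fibroblasts and mesenchyme were higher. Of 42 measured germ cell and meiotic genes, 39 were lower and 3 higher in the knockdown arrays, with a median log2 difference of -0.49, and the list fell against all other genes (camera adjusted p = 1.78e-13). That call is lost with an estimated correlation (adjusted p = 0.243 with an estimated correlation), and it held when any 1 array was left out (highest adjusted p = 6.39e-07). None of its members passed over all genes tested, and 13 fell when adjusted over the list alone.

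The 4 germ cell members of largest change were Tdrd5 (-1.45, SE 0.26), a Tudor protein of the germ granules, Sycp1 (-1.37, SE 0.31) and Sycp2 (-1.04, SE 0.19), parts of the synaptonemal complex, and Slc25a31 (-1.34, SE 0.20), the ADP/ATP carrier of germ cells. Each was lower in all 4 pairs of a knockdown array and its control, and each fell when adjusted over the list alone. Stra8, the gatekeeper of meiosis, had -0.75 (SE 0.26), and Ddx4, a germ cell RNA helicase, -0.32 (SE 0.28); both were picked after their values were seen and neither passed over the list alone. The list of 14 measured reported DAZL target mRNAs, 12 of them lower, fell with a median of -0.15 (camera adjusted p = 0.022; adjusted p = 0.383 with an estimated correlation), though it was called at day 9 and not at day 12. No member passed over the list alone; the largest differences were Suz12 (-0.54, SE 0.15), a Polycomb subunit, Tex19.1 (-0.41, SE 0.13), Sycp3 (-0.40, SE 0.15) and Ddx4. This call ended without the control array of day 9 (adjusted p = 0.250) and without hairpin 2 of day 9 (0.136). The Tex19.1, Sycp3 and Ddx4 genes stand in both lists.

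Among lists that rose, 22 of 24 endoderm markers were higher, with a median of 0.63 (camera adjusted p = 7.67e-07; adjusted p = 0.243 with an estimated correlation). Afp, the alpha-fetoprotein of yolk sac and fetal liver, rose by 2.27 (SE 0.24) when adjusted over the list alone, the only member to do so. Apoa1 (2.22, SE 0.60) and Apob (higher in 3 of 4 pairs), both apolipoproteins, and Cer1 (at least 1.25-fold higher) did not pass. The fibroblast and mesenchyme list, whose genes feeder cells also express, rose with 20 of 23 genes higher and a median of 0.46 (camera adjusted p = 1.05e-06; adjusted p = 0.383 with an estimated correlation). Of its members 3 rose when adjusted over the list alone, among them the proteoglycan Lum (2.16, SE 0.47). The collagen Col3a1 (1.48, SE 0.45), Postn (1.31, SE 0.41) and the crosslinking enzyme Lox (at least 1.79-fold higher) did not.

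Pluripotency factors rose, with 21 of 28 higher and a median of 0.17 (camera adjusted p = 0.0029; adjusted p = 0.289 with an estimated correlation), and 4 members rose when adjusted over the list alone. They were Tdgf1 (1.03, SE 0.19), Nr0b1 (0.92, SE 0.22), Nodal (0.67, SE 0.14) and Pou5f1 (0.70, SE 0.15), the gene whose reporter was used in the sort; the last 2 were picked after their values were seen. Tcl1 (0.97, SE 0.31) and Rif1 (-1.05, SE 0.40) did not pass. Smaller shifts were called for cholesterol biosynthesis (17 of 19 higher, median 0.17, camera adjusted p = 0.0211), mesoderm (16 of 20 higher, median 0.12, camera adjusted p = 0.0278) and ectoderm and neural genes (14 of 19 higher, median 0.08, camera adjusted p = 0.0389). Each had adjusted p = 0.383 with an estimated correlation. Only Stmn2, a neuronal stathmin, passed over its list alone (1.60, SE 0.14). Mvd (0.49) and Dhcr7 (0.35) of the cholesterol list did not, nor did brachyury (T, 0.79), Foxc2 (0.66), Bmp4 (0.47) and Gsc (0.39) of the mesoderm list or Msx1 (0.61), Sox1 (0.53) and Gbx2 (0.43) of the neural list.

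Without the control array of day 9 the number of lists called fell from 8 to 4, and the pluripotency (adjusted p = 0.0526), mesoderm (0.250), neural (0.250), DAZL target (0.250) and cholesterol (0.450) calls ended. The germ cell, endoderm and fibroblast calls held, and the interferon response list, not called with all arrays, was called without that array (adjusted p = 1.89e-05), where the contrast rests on day 12. Without hairpin 1 of day 9 the mesoderm (0.0771), neural (0.0568) and cholesterol (0.0562) calls ended, and the neural call also ended without hairpin 2 of day 9 (0.136) or of day 12 (0.0779). With normexp the pluripotency (0.0568) and cholesterol (0.104) calls ended, while the germ cell, endoderm and fibroblast calls held in every alternative but the estimated correlation.

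The other 20 lists did not pass. Markers of other cell types gave a median of 0.13 (adjusted p = 0.189) for endothelium, 0.16 (0.189) for blood cells, 0.12 (0.700) for heart and muscle and 0.21 (0.432) for gonadal somatic cells; trophectoderm gave -0.08 (0.221). Among early embryo and germline lists, primordial germ cell specification gave 0.03 (0.694), the epiblast and primed state -0.08 (0.727), two-cell stage genes -0.28 (0.160, and 0.033 with the vector as a replicate block), and RNA-binding partners in germ cells, which hold Dazl itself as the only member past the list alone, -0.07 (0.160). Regulators and pathways gave -0.06 (0.180) for Polycomb repressive complexes, -0.13 (0.189) for DNA methylation machinery, -0.04 (0.727) for Hox clusters, 0.03 (0.934) for imprinted genes, -0.04 (0.696) for the cell cycle, and 0.07 (0.190) for hypoxia and glycolysis. Apoptosis gave -0.07 (0.432), p53 targets -0.07 (0.727), cell stress -0.02 (0.702), dissociation and immediate early genes 0.00 (0.694) and the interferon response -0.21 (0.189). The sign of the median differed from that of the mean or of the test for epiblast, imprinted and cell stress genes.

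Gene by gene, limma called 0 of 20220 genes at an adjusted p under 0.05; 2012 genes had an unadjusted p under 0.05 (1034 higher, 978 lower), against 1011 by chance. Other settings called 2 genes (normexp), 8 (strict filter), 1 (mean of probes), 2 (authors' table), 2 (trend and robust prior) and 0 (quantile normalization or no filter). With the vector as a replicate block, 20 genes passed, 10 in each direction, with adjusted p of 0.0104 to 0.0462. In that fit Ambp, a plasma protein precursor (-2.88, SE 0.23), Cyp4f15, a cytochrome P450 (at least 1.96-fold), and the X-linked Asb9 (-2.24, SE 0.15), Tmem255a (-1.87, SE 0.14) and Radx (-1.67, SE 0.14) fell. The plasma proteins Afp (2.27, SE 0.20), Apoa1 (2.22, SE 0.20) and Fgb (2.31, SE 0.15) rose in it, as did Gngt2 (1.54, SE 0.14) and Stmn2 (1.60, SE 0.15). With normexp and no block, Ambp (-1.60), Radx (-0.62), Tmem255a (-0.46) and Gngt2 (0.57) had smaller differences. Cyp4f15 came to 0.11, about the median of all genes in that setting (0.12). Apoa1 and Fgb lie outside the rule for named genes and were chosen after their values were seen.

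None of the other genes named by the rule passed in either fit. On the higher side they were the langerin gene Cd207 (1.55), the receptor Nrp1 (at least 2.29-fold), Mep1b (1.40), Evc (1.32), Kirrel2 (1.21), the neuronal Stmn3 (1.21) and Dab1 (1.09), Kbtbd11 (1.11) and the growth factor Fgf15 (1.05). On the lower side they were the transcription factors Erg (-2.21, well above background on 2 of the 4 knockdown arrays), Gsx2 (-2.13), Lmx1b (-1.31) and Dmrtc1b (-1.61), the adrenergic receptor Adra2a (-1.45) and the RNA export factor Nxf2 (-1.39). Their SE were 0.14 to 0.26 and their adjusted p 0.136 to 0.169 with limma, and each differed the same way in all 4 pairs, as the rule required. Some shrank in an alternative that kept all arrays, at most to -0.24 for Erg, -0.32 for Nxf2, -0.58 for Dmrtc1b, 0.40 for Nrp1 and 0.56 for Kbtbd11. Others shrank less, at most to -1.12 for Gsx2 and 1.16 for Mep1b.

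Genes of chromosome 1 stood lower as a whole in the knockdown arrays, a pattern picked after the values were seen. Over its 846 genes well above background on all 6 arrays, the median log2 difference was -0.22 and -0.27 for hairpins 1 and 2 at day 9, and -0.14 and -0.09 at day 12; over the pairs together 72.7% were lower. Medians of the other autosomes over the pairs together were -0.02 to 0.06, the highest being chromosome 8. Leaving out the genes of chromosome 1, an alternative added after seeing the data, again gave 0 genes and 8 lists, with camera adjusted p = 3.83e-13 for the germ cell list.

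**Figure D2:**
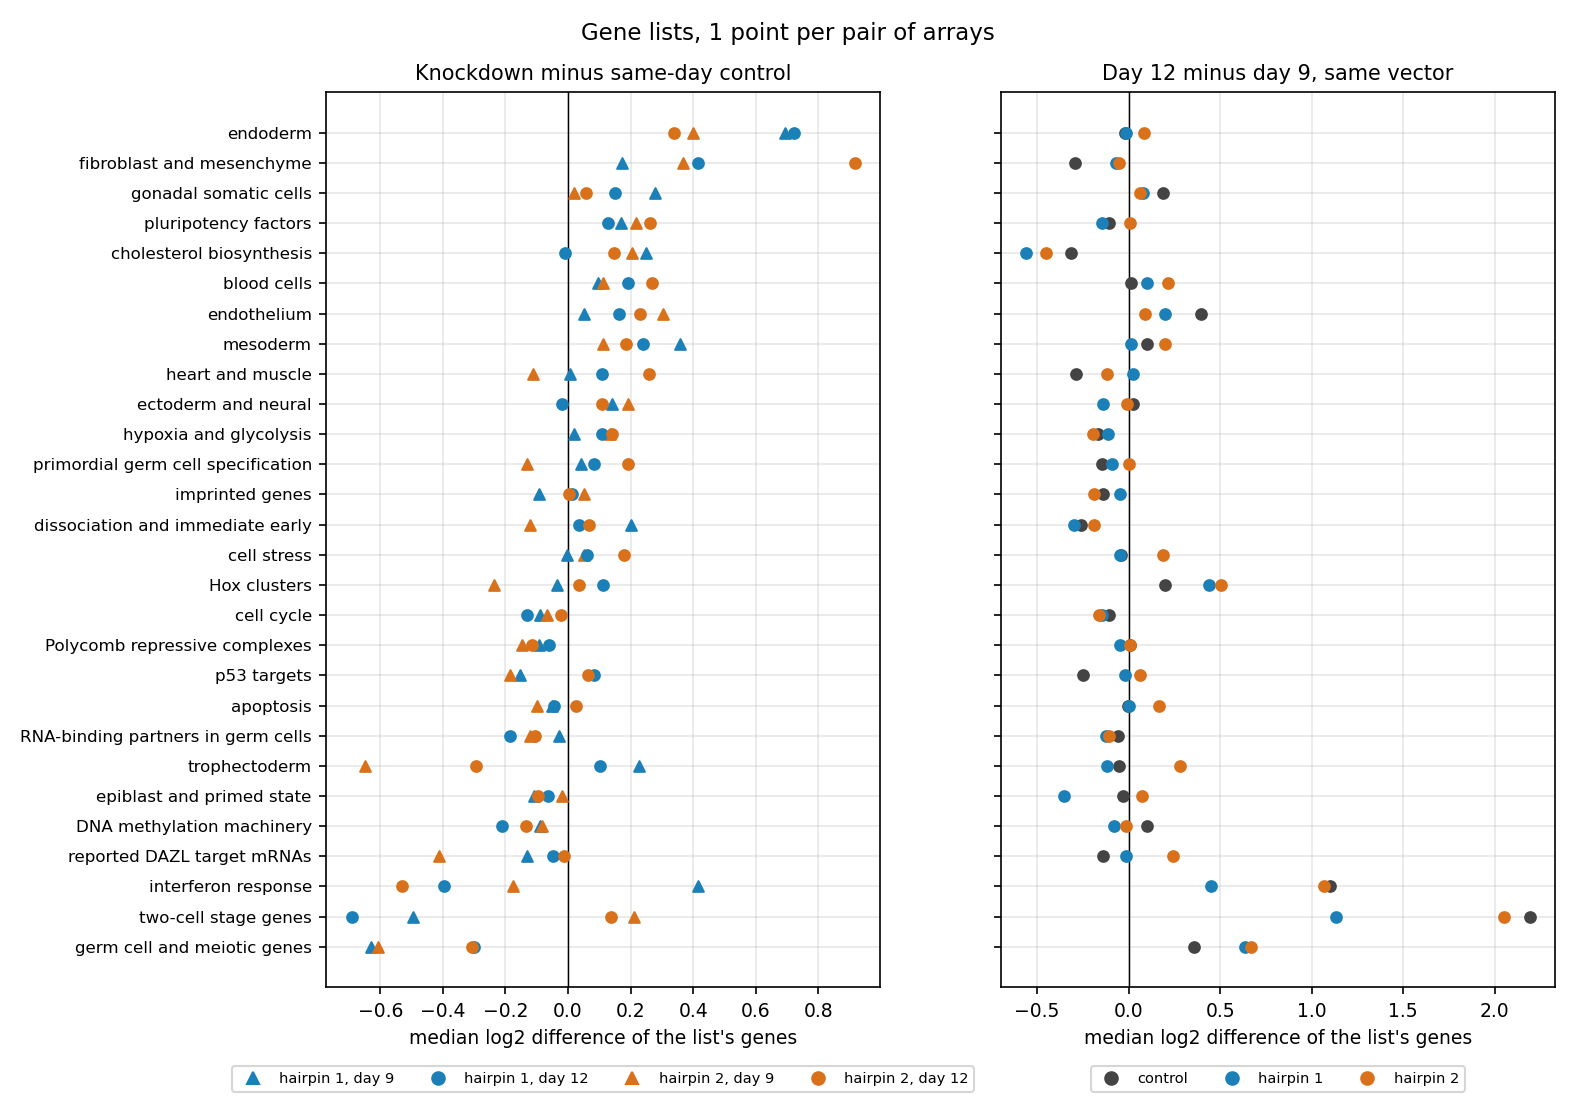
Median log2 difference of each of the 28 gene lists, 1 point per pair of arrays: knockdown minus the control of the same day (left) and day 12 minus day 9 with the same vector (right). The germ cell list lies below 0 in all 4 knockdown pairs and above 0 in all 3 day pairs, and the endoderm list lies above 0 in all 4 knockdown pairs.

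**Figure D3:**
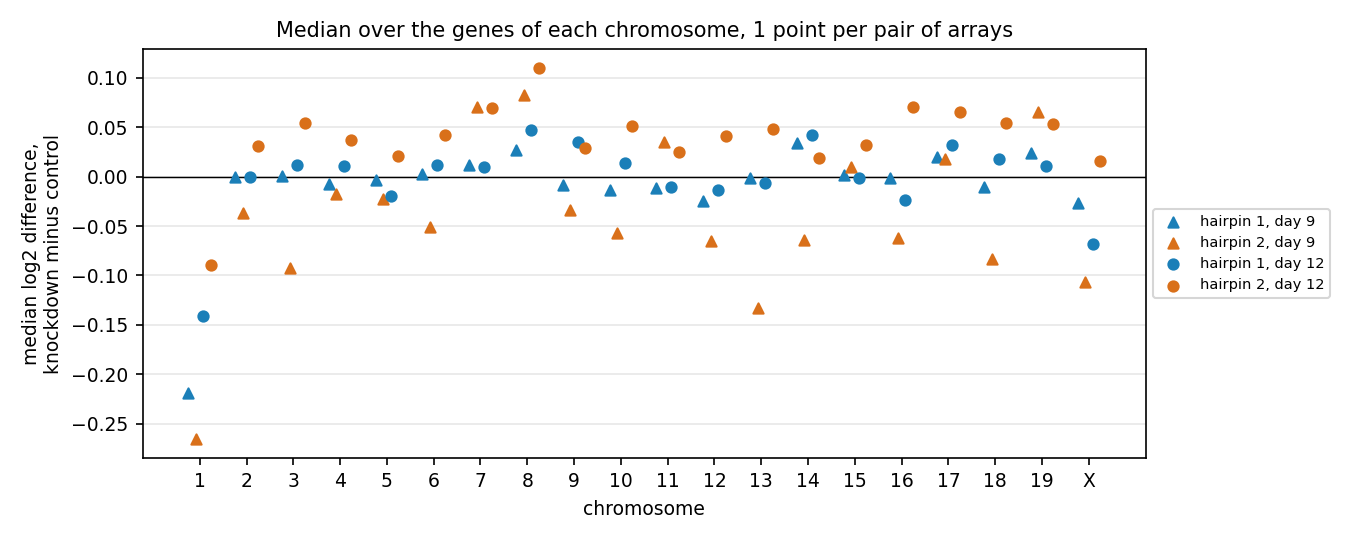
Median log2 difference, knockdown minus the control of the same day, of the genes of each chromosome well above background on all 6 arrays, 1 point per pair of arrays; chromosome Y is not drawn. Chromosome 1 lies lowest, with medians of -0.27 to -0.09.

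Whether the knockdown effect was the same at both days was asked next. At day 9 the germ cell list fell with a median of -0.62 (camera adjusted p = 9.37e-15; 0.293 with an estimated correlation), and at day 12 with -0.35 (6.39e-07; 0.528). The difference itself was called (median 0.26, camera adjusted p = 0.0169; adjusted p = 0.867 with an estimated correlation), but not without hairpin 1 of day 9 (0.338). The interferon response list did not pass at day 9 (median 0.16, adjusted p = 0.152) and fell at day 12 (median -0.54, camera adjusted p = 1.89e-05; 0.618 with an estimated correlation). Its difference was called (24 of 25 genes lower, median -0.67, camera adjusted p = 5.22e-08; adjusted p = 0.867 with an estimated correlation), and it too ended without hairpin 1 of day 9 (0.0501). The other 26 lists gave no called difference (adjusted p of 0.116 to 0.984).

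Other lists were called at 1 or both days. Endoderm genes rose at day 9 (median 0.58, camera adjusted p = 1.07e-05; 0.444 with an estimated correlation) and day 12 (0.64, 4.57e-05; 0.528), and fibroblast genes rose at day 9 (0.25, 0.0013; 0.701) and day 12 (0.72, 6.54e-07; 0.618). Called at day 9 but not at day 12, with no called difference between the days, cholesterol biosynthesis (0.25, camera adjusted p = 0.0018), pluripotency (0.24, 0.0042) and mesoderm (0.15, 0.0213) rose, each with adjusted p = 0.565 with an estimated correlation. Neural genes rose (0.16, 0.0213) and DAZL targets fell (-0.31, 0.0151) at day 9, again without a called difference between the days, each with adjusted p = 0.633 with an estimated correlation. At day 12 mesoderm had a median of 0.17 (adjusted p = 0.250) and pluripotency of 0.16 (0.0526), and the DAZL targets had a median of -0.01, with 7 genes higher and 7 lower (adjusted p = 0.250). Without hairpin 1 of day 9 the endoderm, cholesterol, pluripotency and DAZL target calls (adjusted p = 0.0582 each), the mesoderm call (0.288) and the neural call (0.136) of that day ended. Without hairpin 2 of day 9 the DAZL target (0.0807), neural (0.0850) and fibroblast (0.103) calls ended.

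No gene passed within a day with limma, where 870 genes at day 9 and 1030 at day 12 had an unadjusted p under 0.05, against 1011 by chance, nor did any gene pass for the difference (349). With the authors' deposited values, 1 gene passed at day 9 and 1 for the difference. Dazl had -3.98 (SE 0.40, adjusted p = 0.730) at day 9 and -4.62 (SE 0.40, adjusted p = 0.668) at day 12. The others of smallest p were the olfactory receptors Olfr554 and Olfr706 at day 9 (each at least 1.64-fold lower), and C530030K21Rik (at least 3.88-fold) and AK038710 (at least 2.94-fold higher) at day 12. For the difference they were Trpv6, Olfr722 and Olfr554, for which no size is given, since none was well above background on all 6 arrays.

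Day 12 against day 9 asks how the sorted cells changed as differentiation went on; each day was on a slide of its own. Germ cell and meiotic genes, interferon response genes and genes of the two-cell embryo were higher at day 12, and cholesterol biosynthesis and immediate early genes were lower. With limma 30 genes passed, 24 higher and 6 lower (2435 at an unadjusted p under 0.05), and 328 with the vector as a replicate block, which included all 30. Without hairpin 1 of day 9 the count was 20; without any other array, controls included, it was 0, as it was with no filter, and with normexp it was 1.

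The germ cell list rose, with 38 of 42 genes higher and a median of 0.55 (camera adjusted p = 3.45e-15; adjusted p = 0.206 with an estimated correlation). Of its members 19 rose when adjusted over the list alone, and Slc25a31 (1.96, SE 0.19) also over all genes tested. Asz1 (2.16, SE 0.31) and Piwil4 (1.54, SE 0.25), of the piRNA pathway, and Sycp1 (1.48, SE 0.29) rose over the list alone. The interferon response list rose, with 23 of 25 higher and a median of 0.97 (camera adjusted p = 1.19e-11; adjusted p = 0.380 with an estimated correlation), and 13 members rose over the list alone. They include Ifi44 (at least 3.54-fold), Oas2 (1.65, SE 0.25) and Usp18 (1.62, SE 0.33), while Mx1 (1.76, SE 0.69) did not pass. With normexp both calls held with smaller medians, 0.34 for the germ cell and 0.39 for the interferon list, where all genes had -0.12.

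All 11 measured two-cell stage genes were higher, with a median of 2.20 (camera adjusted p = 4.28e-08; adjusted p = 0.380 with an estimated correlation), and 8 rose over the list alone, among them Zscan4c (3.62, SE 0.45), Tcstv1 (SE 0.59), Tcstv3 (2.73, SE 0.57) and Arg2 (2.63, SE 0.54). With normexp the two-cell call held, but its median was 0.45. Hox genes rose, with 18 of 24 higher and a median of 0.30 (camera adjusted p = 0.0038; 0.380 with an estimated correlation), and 4 rose over the list alone. Hoxa10 (at least 1.66-fold) was among these; Hoxb9 (0.91, SE 0.31) and Hoxb4 (0.81, SE 0.26) were not, and Hoxc9 (0.83, SE 0.20) was. The direction of the Hox list flipped with normexp (adjusted p = 0.352).

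Cholesterol biosynthesis genes fell, with 18 of 19 lower and a median of -0.42 (camera adjusted p = 5.73e-08; adjusted p = 0.206 with an estimated correlation), though no member passed over the list alone, Sqle (-0.63), Idi1 (-0.59) and Fdft1 (-0.58) among them. Dissociation and immediate early genes fell (14 of 20 lower, median -0.20, camera adjusted p = 4.24e-04; 0.394 with an estimated correlation). Of these, Fosb (-1.36, SE 0.13) fell over all genes tested, Egr2 (-1.58, SE 0.18) and Egr1 (-1.17, SE 0.16) fell over the list alone, and Fos (-0.72, SE 0.27) did not pass. Hypoxia and glycolysis genes (20 of 24 lower, median -0.19, camera adjusted p = 0.0058) and cell cycle genes (23 of 33 lower, median -0.16, camera adjusted p = 0.019) fell, each with adjusted p = 0.380 with an estimated correlation and no member past its list. The largest differences were Aldoc (-0.51), Adm (-0.50), Egln1 (-0.49) and Pfkl (-0.32) in the former, and Ccne2 (0.83), Cdk6 (-0.54), Ccnd1 (-0.46) and Plk1 (-0.43) in the latter. The cell cycle call ended without hairpin 2 of day 9 (adjusted p = 0.0780) or hairpin 1 of day 12 (0.0511), with normexp (0.750) and with quantile normalization (0.102). With normexp the immediate early (0.112) and hypoxia (0.750) calls ended as well.

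The other 20 lists did not pass for the day. Pluripotency factors gave a median of -0.15 (adjusted p = 0.153), the epiblast and primed state -0.02 (0.337), primordial germ cell specification -0.10 (0.563), reported DAZL targets 0.00 (0.925) and RNA-binding partners -0.04 (0.768). Polycomb gave -0.04 (0.972), DNA methylation machinery 0.02 (0.993), apoptosis 0.04 (0.768), p53 targets -0.08 (0.153), cell stress 0.04 (0.925) and imprinted genes -0.14 (0.0788). Markers of other cells gave 0.15 (0.687) for mesoderm, -0.01 (0.972) for endoderm, -0.13 (0.334) for neural genes, -0.01 (0.687) for trophectoderm and -0.13 (0.216) for fibroblasts. Endothelium gave 0.18 (0.132), blood cells 0.05 (0.730), heart and muscle -0.10 (0.137) and gonadal somatic cells 0.05 (0.656). The sign of the median differed from that of the mean or of the test for DAZL targets, RNA-binding partners, Polycomb, DNA methylation, endoderm and trophectoderm.

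Among the named genes that passed over all genes tested, the interferon-induced Ifi27 rose most (2.48, SE 0.24, adjusted p = 0.0400), with log2 values of 5.14 ± 0.26 (SD, n = 3) at day 12 and 2.66 ± 0.45 (SD, n = 3) at day 9. Lgals6 (2.28, SE 0.13) and the keratin Krt23 (2.13, SE 0.14) followed, and the X-linked testis genes Ssxb1 (1.98, SE 0.12), Ssxb2 (1.77, SE 0.14) and Nxf2 (1.96, SE 0.15) rose too. Fam151a (1.98), Rasgef1c (1.78), the T cell receptor gamma gene Tcrg (1.78), Pramel34 (at least 1.74-fold) and the acrosomal gene Acrv1 (at least 2.17-fold) also passed; the last 2 lie near background and flipped with normexp (-0.23 each). None of the genes named as passing kept its call with normexp, where Fam151a (0.06), Rasgef1c (0.14) and Ssxb2 (0.16) came close to 0, and Nxf2 (0.49), Ssxb1 (0.73) and Krt23 (0.97) also shrank, while Ifi27 stayed at 2.53 (adjusted p = 0.0867). Besides Fosb, the matrix protein gene Fras1 (-1.94, SE 0.15), the cytokine gene Il16 (-1.43, SE 0.13), Dhrs2 (at least 1.39-fold, well above background on 2 of 3 arrays of day 9) and Macc1 (-1.20, SE 0.12) fell. The chemokine gene Cxcl12 (-1.19), Tfap2e (-1.45), Crb2 (-1.18), the imprinted Dlk1 (-1.21), Olfr1122 (-1.14), Egr1 and Egr2 did not pass over all genes (adjusted p of 0.0613 to 0.108).

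Hairpin 2 against hairpin 1 shows how far the knockdown lines differ from each other, with each hairpin measured once per day and numbered as in the sample titles, from which the raw files' names differ. Trophectoderm genes were lower with hairpin 2, as were Aqp8 and Gkn2 of gut and stomach epithelium, while the stomach gene Pga5 was higher. The trophectoderm list fell (14 of 18 lower, median -0.68, camera adjusted p = 8.04e-07; adjusted p = 0.650 with an estimated correlation); the regulator Cdx2 (-2.26, SE 0.19) fell over all genes tested, and Elf5 (-1.58, SE 0.17), Gata2 (-1.17, SE 0.21) and Tpbpa (-1.11, SE 0.31) fell over the list alone, where 9 did. Two-cell stage genes (11 of 11 higher, median 1.18, camera adjusted p = 5.72e-06; 0.650 with an estimated correlation) and fibroblast genes (20 of 23 higher, median 0.41, camera adjusted p = 5.49e-05; 0.650 with an estimated correlation) rose. Of the former 6 rose over the list alone, among them Tcstv1 (1.56), Tcstv3 (1.53) and Arg2 (1.41); of the latter, with Dcn (1.31), Lum (1.20), Col3a1 (1.04) and Postn (0.99), none did. Interferon response genes (median -0.46, camera adjusted p = 1.43e-04) and immediate early genes (median -0.17, camera adjusted p = 0.0395) fell, with adjusted p = 0.939 each with an estimated correlation. Mx1 (1.20), Ifih1 (-1.01), Isg15 (-0.98) and Ifi44 (-0.75) of the former and Myc (-0.93), Fos (-0.59), Junb (-0.47) and Nr4a1 (-0.34) of the latter did not pass over their lists. The interferon call ended without hairpin 1 of day 9 (0.540) or hairpin 2 of day 12 (0.586), the fibroblast call without hairpin 2 of day 12 (0.0634), and the immediate early call without any 1 array (0.0634 to 0.619). The other 23 lists did not pass (adjusted p of 0.306 to 0.962), the germ cell list with a median of 0.03 (adjusted p = 0.859) among them. In the endoderm list (adjusted p = 0.505), 4 members rose and 8 fell when adjusted over the list alone.

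With limma 14 genes passed, 5 higher and 9 lower (2360 at an unadjusted p under 0.05). Cd5 (3.65, SE 0.21), the pepsinogen Pga5 (2.36, SE 0.17) and Cd99 (1.88, SE 0.16) were higher with hairpin 2. The gastrokine Gkn2 (-7.36, SE 0.58), the water channel Aqp8 (-4.46, SE 0.19), Phgr1 (-3.59, SE 0.31), Crct1 (-2.84, SE 0.25) and Dppa1 (at least 2.43-fold) were lower; Dppa1 lies near background and flipped with normexp (0.35). Gkn2 and Phgr1 were well above background on only 1 of the 2 hairpin 2 arrays, so their differences rest partly on signals not above background, and with normexp they were -3.66 and -0.38, the latter no longer called. The count was 0 without hairpin 2 of day 9 and 0 without hairpin 2 of day 12, 183 without hairpin 1 of day 9, 354 without hairpin 1 of day 12, and 819 without either control. Other settings gave 119 (normexp), 71 (trend and robust prior), 51 (strict filter), 42 (authors' table), 2 (mean of probes) and 1 (quantile normalization or no filter).

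Across 20220 genes, which are not independent replicates, the knockdown effects of day 9 and day 12 had Pearson's r of 0.38 and Spearman's rho of 0.31. With hairpin 1 in the control's place r was 0.54 and rho 0.48, and with hairpin 2 in that place r was 0.26 and rho 0.18. By construction these r equal those of the arrays with the same vector in the check for the replicate block, so they are not separate evidence. With the control in its own place, r was 0.20 without hairpin 1 of day 9 and 0.24 with no filter. In all 4 pairs, 61 genes differed at least 2-fold the same way, 26 higher and 35 lower; among them were Afp, Apoa1, Fgb, Lum, Tdrd5 and Dazl. A simulation with no effect gave 17.5 on average (8 to 29), and putting hairpin 1 or hairpin 2 in the control's place gave 84 and 36. The count was 9 with normexp, and with 1 array less, which leaves fewer pairs to meet, 289 without the control of day 9, 240 without that of day 12, 108 and 103 without hairpin 2 of day 9 and day 12, and 95 without hairpin 1 of day 9.

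At an unadjusted p under 0.05, 2012 genes set the control apart, 1812 hairpin 1 and 1807 hairpin 2; 0, 0 and 1 gene passed, and 8, 6 and 5 lists. The germ cell list had a median of -0.49 with the control in its own place, and of 0.23 and 0.16 with hairpin 1 or hairpin 2 there.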

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

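The tests of dilution and of the choice of control were picked after the result was seen, and the test of a slower gain before.

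The knockdown effect on the interferon response list differed between the days (camera adjusted p = 5.22e-08 for the difference, median -0.67, 24 of 25 genes lower). Relative to each gene's mean over the 6 arrays, the list's median was -0.57, -0.16 and -0.81 for control, hairpin 1 and hairpin 2 at day 9, and 0.74, 0.39 and 0.24 at day 12. The germ cell and meiotic list also differed (camera adjusted p = 0.0169), with -0.62 at day 9 and -0.35 at day 12. Both differences were lost with an estimated correlation (adjusted p = 0.867) and without hairpin 1 of day 9 (0.0501 and 0.338).

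The germ cell list was lower in all 4 pairs of a knockdown array and its control. Dilution by somatic cells as the only source is argued against by the pluripotency factors. Their lowest pair median was 0.1282, above the highest of the germ cell list (-0.30). With normexp the knockdown median was 0.14 for pluripotency factors, near the 0.12 of all genes, and -0.33 for the germ cell list. In that setting the pluripotency factors did not fall, but they rose little beyond other genes. A part played by admixed cells stays open, since fibroblast (pair medians of 0.17 to 0.92) and endoderm genes (0.34 to 0.72) were higher in all 4 pairs although the sort was to remove such cells, and undifferentiated cells with the Oct4 reporter would raise pluripotency factors. Between the days the list gained 0.64 and 0.67 with hairpins 1 and 2 and 0.36 in the control, so no slower gain was seen, but a later start before day 9 stays open: hairpin arrays of day 12 differed from the control of day 9 by 0.01 and -0.01, and correlations across its genes of one hairpin's knockdown difference with the other's day difference were -0.47, -0.17, -0.43 and -0.1152, not all under the -0.3 set for a slower gain. A difference between vectors with no link to Dazl cannot be told apart from a Dazl effect, since only 1 control vector was measured: of 9 ways to choose 1 array per day as the control, 1, the real choice, gave a list median of -0.49 and the next lowest was -0.27, but 9 choices are too few for a share under 0.05. Position on the slide went with the vector on both days, so an effect of position stays open as well. A Dazl effect may therefore be 1 of the open explanations, and a second control vector would be needed to test it.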

How the results depend on the processing

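Signal over background limits the dim genes. The results that changed sign did so with normexp, which shrinks dim signals. The single genes among them lie near background, though the cause was not tested. Over days they were the Hox list (camera adjusted p = 0.352), Pramel34 (-0.23) and Acrv1 (-0.23). At day 9 they were Olfr554 (0.26) and Olfr706 (0.32), for the difference Olfr722 (-0.16) and Olfr554 (-0.18), and between hairpins Dppa1 (0.35). Cyp4f15 changed sign for the knockdown too (0.11), but it lay near the median of all genes with normexp (0.12), so no reversal is shown. For the knockdown, where limma called 0 genes, normexp called 2, the strict filter 8, the mean of probes 1, the authors' values 2, the replicate block 20 and the trend with a robust prior 2. Dazl passed in the same settings, with -3.74, -4.30, -4.51, -4.25, -4.30 and -4.30. With the authors' values 1 gene was called at day 9 and 1 for the difference between days. Over days normexp called 1 gene, no filter 0 and the replicate block 328, and leaving out 1 array gave 0 to 20. Between hairpins normexp called 119 genes, quantile normalization 1, the strict filter 51, no filter 1, the mean of probes 2, the authors' values 42 and the trend with a robust prior 71, and leaving out 1 array gave 0 to 819. With an estimated correlation 0 lists were called for the knockdown and 0 over days; normexp called 4 lists over days, and leaving out 1 array gave 4 to 9 lists for the knockdown. The correlation of the day 9 and day 12 effects was 0.24 with no filter and 0.20 to 0.47 with 1 array left out. Genes at least 2-fold in all 4 pairs were 9 with normexp and 67 to 289 with 1 array left out, where fewer pairs have to be met. For some settings the construction shows why: fewer pairs, the spread between hairpins taken out by the block, or few degrees of freedom with an estimated correlation. For lists whose estimate lay above the preset, correlation between genes may add to the loss. For the other settings the cause was not tested. Of the single lists' other values, 121 kept direction and side of the threshold and 22 lost the call, and with 1 array left out 83 kept them and 13 lost the call. Of the named genes' values, 442 kept both, 25 gained a call and 68 lost it, and with 1 array left out 259 kept both and 113 lost the call. Slide as a block of its own could not be fitted beside day, and the replicate block was not fitted within a day, for the difference between days or for the hairpins.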

Other observations

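The tests of chromosome 1, of the slide and of other splits of the arrays were picked after the result was seen, and the test on Rhox and Magea genes before.

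Most genes of the Y chromosome, or shared by X and Y, separated the hairpins. Of 10 well above background on at least 4 arrays, 9 were higher with hairpin 2 than with hairpin 1 on both days, and 9 were lower with hairpin 1 than in the control on both days. With hairpin 2, 6 were higher than the control at day 9 and 9 at day 12; Gm20738 was the exception to each count of 9 (0.52 and 0.35 with hairpin 1, -0.25 and -0.32 with hairpin 2). Against the control of the same day, Ddx3y had log2 differences of -0.96 and -0.88 for hairpin 1 at days 9 and 12, and of 1.09 and 0.62 for hairpin 2. Eif2s3y had -0.75 and -0.84 for hairpin 1 and 0.41 and 0.91 for hairpin 2, and Uba1y had -1.31 and -1.22 for hairpin 1 and 0.06 and 0.79 for hairpin 2. These 3 were chosen after their values were seen, and no test was run on the set.

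Rhox and Magea genes, families of the X chromosome that DNA methylation keeps silent in most tissues, were mostly higher at day 12. Of 15 measured, 7 Rhox and 8 Magea genes, 13 were higher and 11 in all 3 pairs of arrays with the same vector, with pair medians of 1.31 for the control, 0.62 for hairpin 1 and 1.35 for hairpin 2. Rhox13 had a day difference of 1.37 (SE 0.21), Rhox2a 2.35 (SE 0.39) and Rhox3a 1.37 (SE 0.20), with limma adjusted p of 0.0990, 0.104 and 0.0954, and no member passed.

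The shift of chromosome 1 was weighed against its sources. If a change in copy number differed between the control and hairpin lines, every stretch of the chromosome would shift: with its genes in order and divided into 5 equal parts, the medians were -0.19, -0.18, -0.1486, -0.19 and -0.18, all below the lowest median of another autosome (-0.02). An intensity artifact of dim genes would spare bright ones, but genes brighter than the chromosome's median had -0.2009 (bootstrap 95% interval -0.23 to -0.18) and dimmer ones -0.13. The split by brightness does not test scaling, which would move all chromosomes. Medians of the other autosomes over the pairs together were -0.02 to 0.06, which argues against it. In single pairs they spread wider, down to -0.13 for chromosome 13 with hairpin 2 at day 9, where chromosome 1 had -0.27. Of genes lower in knockdown at an unadjusted p under 0.05, 17.3% (138 of 799) lay on chromosome 1, against 5.57% of all genes with a chromosome and 2.19% (19 of 868) of those higher. The hairpins differed from each other by -0.06 at day 9 and 0.04 at day 12, so a hypothesis is that part of the control cells may carry an extra copy, which DNA from these lines could test.

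The rise of interferon, two-cell and germ cell genes at day 12 was weighed as well. A slide or scan effect cannot be told apart from day, since the interferon list's difference of 0.9719 is also a difference between slides; with normexp it was 0.39. A loss of DNA methylation between the days would raise other genes it silences, and the 15 Rhox and Magea genes had a median day difference of 0.924 (camera p = 4.42e-07; p = 0.102 with an estimated correlation), where under 0.2 would have spoken against it. Such a loss would give this, but the genes were measured on the same slides, which leaves a slide effect open. All but Magea9-ps (0.13) were also lower in the knockdown arrays, as most of the germ cell list was. A rise along with other germ cell genes therefore cannot be told apart from a loss of methylation here. Only 10 of the 15 were well above background on all 6 arrays, and methylation itself was not measured.

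Of the 10 ways to split the 6 arrays into 3 and 3, 2, the real one included, gave as many called genes as day 12 against day 9 (30), and 10 splits are too few for a share under 0.05. The other of these 2 set both controls and hairpin 2 of day 9 against the other knockdown arrays. With knockdown as a term, as in the day contrast, such a split compares hairpin 2 of day 9 alone with the other knockdown arrays. Pearson's r of that array with each other array was 0.983 to 0.987, highest with the control of day 9 and lowest with the control of day 12. These values do not place it nearer to the controls as a group or farther from them. What sets it apart was not tested. The 3 other splits that part all 3 pairs with the same vector gave 0 genes each; with the vector as a replicate block the real split gave 328.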
